A study of Mus musculus with 30 samples.

How the data were processed

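Muscle and kidney of 15 mice aged 6 weeks were profiled, with 1 array for each tissue of each animal. The animals were wild type or Kif3aΔTub, a mutant that lacks the kinesin-2 motor subunit Kif3a in kidney tubules, where it is needed to build primary cilia. Each genotype received PBS or sActRIIB-Fc, a soluble activin receptor IIB fusion protein that binds activins and related ligands and is called the trap here. Per the labels, the trap was injected into the peritoneum weekly at 10 mg/kg, with 2 injections up to week 6. Each tissue had 3 untreated wild-type arrays and 4 arrays in each of the other groups. Genotype, treatment and tissue were taken from the labels, and the animal number in the sample titles tied the tissues of an animal together.

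RNA was extracted from snap-frozen tissue with QIAZOL, labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The values used were the authors' deposited normalized log2 intensities, 1 per probe set and array. The log base was read from the values, and the normalization method is not given in the sources used here. Array medians lay between 5.94 and 6.06 in muscle and between 6.09 and 6.24 in kidney. No further scaling, background step or filter on low values was applied, and the number of arrays limits the precision. Arrays of the same group correlated across genes at 0.977 or more. The labels give no batch.

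The table held 35088 probe sets, of which 31563 were annotated to 1 gene symbol, 825 to several and 2700 had no gene listed. Only those with 1 symbol were used, giving 17782 genes. Symbols were checked against RefSeq, where 111 had no match and were kept as annotated, and 0 changed. Each gene was represented by its probe set with the highest mean over the 15 arrays of the tissue. The fit of both tissues together took the highest mean over all 30 arrays, which can be another probe set.

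Each tissue was fitted apart with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and a shared, moderated estimate of the spread. The comparisons were mutants against wild type under PBS and under the trap, trap against PBS in each genotype, the interaction of genotype and trap, and treated mutants against untreated wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the tissue. The difference between tissues in the genotype effect was tested in 1 fit of all 30 arrays with the animal as a random block (consensus correlation 0.0749).

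A total of 44 gene lists were tested in both tissues, covering muscle structure and wasting, kidney segments and injury, other cell types, growth factor signalling, metabolism, stress and immunity. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, with at least 5 members measured. The same test with an estimated correlation and the self-contained test fry stand beside it. Correlations of fold changes across genes were set beside simulated unchanged groups, and correlations across animals were tested by permutation.

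The genes named were chosen by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap between the groups, the top 2 called members of each called list, and 13 further genes of the activin pathway, muscle wasting and kidney injury that were analysed. Comparisons other than genotype under PBS and trap in mutants take the 5 largest in each direction and those of the 13 that were called. Genes named outside the rule are marked as chosen after their values were seen. Mstn, Gdf11 and Gdf15 are not analysed here.

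Alternatives were the mean of all probe sets of a gene, only genes above the median level, quantile normalization, median centring, array weights, a trended prior variance, a fit of only the compared groups, the replicate number as a block, a 2-fold minimum, other set tests and leaving out each array in turn. Covariates from the 18S ribosomal RNA control probe set and from the 3 prime minus 5 prime signal of the actin control probe sets were added after the data were seen, the latter because it differed between the genotypes under PBS. The permutation of the 18S signal within each genotype was also chosen after the group means were seen. Group labels were also reassigned over the arrays compared, in up to 100 splits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

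The steps were tested on simulated data made for genotype under PBS, with 200 of 17782 genes changed. In muscle 84% of genes changed by 1 and 99% of those changed by 2 on the log2 scale were recovered, with 16 false calls. In kidney the shares were 89% and 100%, with 8 false calls. With nothing changed limma called 0 genes, and a list shifted by 0.5 was the only list called. The simulated genes were drawn independently of each other, so this does not check the list test on genes that vary together. On the real arrays, reassigned group labels gave a median of 11.5 to 18 called lists.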

Results

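Expression of 17782 genes was compared in muscle and kidney of 15 mice aged 6 weeks, on 30 arrays. In each tissue 3 untreated wild-type animals, 4 untreated mutants, 4 wild-type animals given the trap and 4 mutants given the trap were measured. The mutants lacked Kif3a in kidney tubules. The design asked how their kidney disease was reflected in muscle and what the trap, which binds activins and related ligands, changed. Changes below are log2 fold changes ± standard error from limma, group levels are mean log2 intensities ± SD, and adjusted p values are from the same fits. Signal on an array gives no count of molecules, so the number of animals sets the precision.

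Kif3a itself was lower in untreated mutant kidneys, at 7.33 ± 0.12 against 7.83 ± 0.07 in wild type (-0.50 ± 0.15, n = 4 and 3, adjusted p = 0.011). Its 3 probe sets gave -0.50, -0.41 and -0.41. In treated kidneys the mutants were at 7.63 ± 0.30 and the wild type at 7.65 ± 0.22 (-0.02 ± 0.14, adjusted p = 0.91). In muscle the genotypes were at 7.18 ± 0.33 and 7.32 ± 0.38 under PBS (-0.15 ± 0.18, adjusted p = 0.658). Where the probe sets lie relative to the deleted part was not given in the sources used here, and a probe set outside it checks nothing about the deletion. The kidney also holds cells other than tubule cells.

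In untreated mutant kidneys, injury genes were far above wild type and transporters of the proximal tubule far below. Lcn2, a secreted siderophore-binding protein used as a marker of tubule injury, rose by 8.12 ± 0.23, from 5.27 ± 0.25 to 13.39 ± 0.38 (n = 3 and 4, adjusted p = 5.22e-12). Timp1, an inhibitor of matrix metalloproteinases, rose by 4.62 ± 0.46, Socs3, a feedback inhibitor of cytokine signalling, by 4.94 ± 0.26, and Col12a1, a collagen chain, by 5.64 ± 0.33. Sprr2f, Muc4, Egr2 and Il18r1 completed the 8 largest rises (4.44 to 5.73). The largest falls were in the organic anion transporter genes Slc22a30 (-7.00 ± 0.36), Slc22a19 (-6.37 ± 0.32), Slc22a22 (-5.84 ± 0.56) and Slco1a1 (-5.58 ± 0.82), and in Akr1c14, an aldo-keto reductase (-7.00 ± 0.70). Dnase1, a secreted deoxyribonuclease, fell by 6.01 ± 0.44, Egf, made in the distal tubule, fell by 5.67 ± 0.59, and Acsm3, an acyl-CoA synthetase, fell by 5.27 ± 0.70. For all 16 genes the arrays of the groups did not overlap, and adjusted p was at most 4.13e-05. In 4 of the 8 rises and 3 of the 8 falls the dimmer group lay at or under 5.07, the mean signal of fast-fibre muscle genes in kidney, so these changes may be understated and their order is no ranking. The mean of all probe sets gave 2.81 for Col12a1 and 3.12 for Muc4, still called.

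Markers of macrophages and myeloid cells rose in untreated mutant kidneys in all 25 measured members (median 3.38), led by the lysozymes Lyz2 (18.4-fold) and Lyz1 (4.17 ± 0.24). Tubule injury genes rose in 22 of 23 (median 2.65), matrix genes in 29 of 31 with 1 lower (2.07), and targets of TGF-beta and SMAD2/3 in 18 of 18 (2.46), among them Ccn2, a matricellular growth factor (3.48 ± 0.34). Genes of NF-kB, cytokines and chemokines rose in 22 of 24 (1.62), such as the adhesion molecule Vcam1 (3.88 ± 0.32). The complement list had 13 of 19 higher and 1 lower (1.86), with the C1q chains C1qb (4.09 ± 0.24) and C1qc (4.04 ± 0.23). Counts adjusted over the list alone were the same for these 6 lists, and camera placed each past the threshold (adjusted p = 1.8e-06 or lower). With an estimated correlation none of the 6 was called: adjusted p = 0.0956 for tubule injury and complement, 0.15 for TGF-beta and NF-kB, 0.158 for macrophages and 0.205 for matrix with an estimated correlation.

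Proximal tubule genes fell in 28 of 29 members in untreated mutant kidneys (median -2.42), and those of oxidative phosphorylation fell in 35 of 37 (-0.84), including Cox7a1 (-1.96 ± 0.25) and Ndufs1 (-1.72 ± 0.13), subunits of complex IV and complex I. Fatty acid oxidation and PPAR targets fell in 19 of 24 (-0.86), with the fatty acid transporter Cd36 at -3.41 ± 0.58 and the peroxisomal enzyme Ehhadh at -2.57 ± 0.39. Of the loop of Henle and distal tubule list 11 of 16 were lower and 2 higher (-0.69), and the thiazide-sensitive transporter Slc12a3 fell by 2.98 ± 0.19 (-1.86 with the mean of its probe sets). Collecting duct genes went the other way in 18 of 23, with 3 lower (1.79), led by the keratin Krt18 (4.08 ± 0.20) and the transcription factor Elf5 (3.12 ± 0.18). Adjusted over the list alone the counts were the same. With an estimated correlation these calls were lost as well: adjusted p = 0.158 for proximal tubule and collecting duct, 0.205 for oxidative phosphorylation and 0.269 for the other 2 lists with an estimated correlation.

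Growth factor genes of the activin and BMP pathway were higher in 20 of 28 members and lower in 1 in untreated mutant kidneys (median 0.84, 21 higher when adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). Inhba, which encodes the subunit of activin A, rose by 1.54 ± 0.12, from 5.42 ± 0.19 to 6.96 ± 0.07 (n = 3 and 4, adjusted p = 1.08e-07). Fst, the activin antagonist follistatin, rose by 1.47 ± 0.18, and Fstl1, a secreted follistatin-like protein, by 2.70 ± 0.20. Inhbb, the subunit of activin B, rose by 3.32 ± 0.29 on the probe set with the higher mean signal in kidney, while its other probe set gave 0.02 ± 0.12 and the mean of the probe sets 1.67. Circulating factors linked to cachexia were higher in 11 of 21 members and lower in 3 (median 0.67, the same counts adjusted over the list alone, adjusted p = 0.269 with an estimated correlation). That list was not called when only genes above the median level were used (median 1.27). Myc, a growth regulator, rose by 2.10 ± 0.21 and Atf4, a stress-response transcription factor, by 0.54 ± 0.13. The ubiquitin ligase gene Fbxo32 rose by 1.91 ± 0.33 (1.19 with the mean of its probe sets) and Trim63, another ligase of muscle wasting, fell by 3.29 ± 0.39. Havcr1, which encodes the injury marker KIM-1, gave 0.03 ± 0.36 (adjusted p = 0.945), Acvr2b 0.16 ± 0.14, Id1 0.52 ± 0.28 and Fbxo30 -0.26 ± 0.26, none of them called.

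The remaining lists called in this kidney comparison were ribosomal proteins (median 0.59, 18 of 20 higher, led by Rpl35 and Rps19 at 1.00 ± 0.12 and 0.91 ± 0.09), fibroblast, pericyte and smooth muscle markers (1.07, 14 of 18 higher, with Thy1 at 3.08 ± 0.27 and Tagln at 3.03 ± 0.31) and heat shock and immediate-early genes (1.33, 15 of 21 higher and 2 lower, with Fos at 3.21 ± 0.25). Interferon response genes were higher in 16 of 26 (0.71, Psmb8 1.69 ± 0.17 and Ifit1 1.65 ± 0.32). Genes of p53 and senescence were higher in 9 of 15 and lower in 1 (0.92), with the cell cycle inhibitors Cdkn2b at 2.64 ± 0.24 and Cdkn1a at 2.57 ± 0.34. Glucocorticoid targets were higher in 11 of 20 and lower in 2 (1.12), with the transcription factor Cebpd at 2.84 ± 0.24. The p53 and glucocorticoid lists were not called when only genes above the median level were used, and the p53 median was 0.55 with the mean of all probe sets. Adjusted over the list alone the counts higher were 18, 14, 16, 17, 9 and 15. None was called with an estimated correlation (adjusted p = 0.158 to 0.517 with an estimated correlation). Fry, which does not compare a list with the other genes, called all 19 lists that camera called in this comparison. Over all genes 9174 were called, 4420 higher and 4754 lower, and 2716 of them changed at least 2-fold. Centring each array on its median gave 3842 higher and 6531 lower of 10373. That centring takes out a shift of 0.09 in this comparison, 0.11 between the genotypes under the trap and 0.10 between treated mutants and untreated wild type, and the changes given here are before it.

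**Figure D1:**
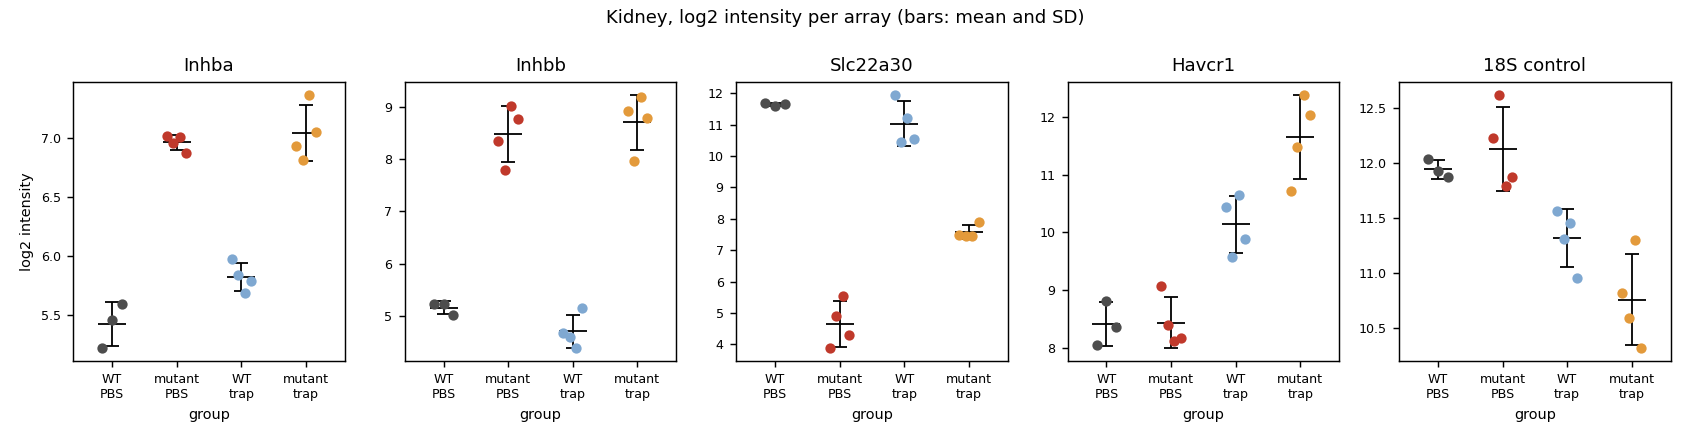
Log2 intensity of Inhba, Inhbb, Slc22a30, Havcr1 and the 18S ribosomal RNA control probe set in each kidney array (points) for 4 groups, with bars for mean and SD. Inhba was at 5.42 in untreated wild type and 6.96 in untreated mutants, Havcr1 was higher in both treated groups, and the 18S control was lower in all 8 treated than in all 7 untreated kidneys.

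In muscle of untreated mutants, the collagens Col1a1 and Col3a1 and the tendon gene Tnmd were far below wild type. Col1a1, a chain of type I collagen, fell by 3.93 ± 0.27, from 11.25 ± 0.05 to 7.33 ± 0.64 (n = 3 and 4, adjusted p = 2.06e-07), and Col3a1, the chain of type III collagen, fell by 3.13 ± 0.33. Kera, the proteoglycan keratocan (-4.56 ± 0.27), Tnmd, the tendon protein tenomodulin (-3.88 ± 0.26), Aplnr, the apelin receptor (-3.96 ± 0.37), Wif1, a secreted Wnt inhibitor (-3.54 ± 0.28), Col4a5, a basement membrane collagen (-3.43 ± 0.21), and Ecrg4 (-3.14 ± 0.21) completed the 8 largest falls. The largest rises were in Slc15a2, a peptide transporter (3.78 ± 0.69), Arrdc2, an arrestin-domain gene (3.75 ± 0.65), S100a8, a calcium-binding protein of neutrophils (3.03 ± 0.51), Cebpd (2.96 ± 0.44), Ddit4, an inhibitor of mTORC1 (2.74 ± 0.69), Arhgap26 (2.65 ± 0.49), Pik3r1, a regulatory subunit of PI3-kinase (2.64 ± 0.29), and the metallothionein Mt1 (2.54 ± 0.60). Arrays of the groups did not overlap for any of the 16 genes, and adjusted p was at most 0.0126. In 3 of the 8 rises and 5 of the 8 falls the dimmer group lay at or under 5.52, the mean signal of proximal tubule genes in muscle, so these changes may be understated and their order is no ranking. The mean of all probe sets gave 1.17 for Slc15a2, 0.98 for Arhgap26 and -2.18 for Col4a5, still called.

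Matrix genes fell in 25 of 31 members in untreated mutant muscle (median -1.48, 27 lower when adjusted over the list alone), and markers of fibroblasts, pericytes and smooth muscle fell in 9 of 18 (-0.71, 10 lower and 1 higher alone), among them the surface protein Thy1 (-2.66 ± 0.22). Glucocorticoid targets rose in 14 of 20 (median 1.53, 15 alone), with Cebpd, Ddit4 and Pik3r1 given above. Interferon response genes fell in 13 of 26 (-0.58, 16 lower and 1 higher alone), including the GTPase Iigp1 (-1.97 ± 0.45) and the chemokine Cxcl9 (-1.74 ± 0.29, or -1.04 with the mean of its probe sets). Camera called all 4 lists (adjusted p = 3.14e-06 or lower), and none was called with an estimated correlation: adjusted p = 0.143 for matrix and 0.179 for the other 3 with an estimated correlation.

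Genes of muscle wasting were higher in untreated mutant muscle in 10 of 22 members of the list of ubiquitin ligases and FoxO genes, with 1 lower (median 0.51, 13 higher and 1 lower adjusted over the list alone, adjusted p = 0.179 with an estimated correlation). Fbxo32, the ligase atrogin-1, rose by 1.67 ± 0.54 (9.90 ± 0.53 to 11.57 ± 1.41, n = 3 and 4, adjusted p = 0.0454), and Trim63, the ligase MuRF1, rose by 0.94 ± 0.29 (adjusted p = 0.0373). Untreated mutant replicate 1 had Fbxo32 at 13.5 and the other 3 between 10.2 and 11.6, and without it the change was 1.02 (adjusted p = 0.0794, not called), while Trim63 was at 0.58 (adjusted p = 0.0495). The call of Fbxo32 was lost in 17 of 26 other settings and that of Trim63 in 9 of 26. Eif4ebp1, a repressor of translation, rose by 1.44 ± 0.27. Lcn2 rose by 2.46 ± 0.63, with untreated mutant replicate 1 at 10.0 and the other 3 between 6.06 and 6.87 against 4.85 ± 0.13 in wild type, and by 1.56 without replicate 1. Of the pathway genes, Fst fell by 0.67 ± 0.20 and the target Id1 rose by 0.97 ± 0.29, each lost in 7 of 26 settings, and the receptor Acvr2b rose by 0.53 ± 0.17 (adjusted p = 0.0471, lost in 17 of 26 settings). Not called were Inhba (-0.30 ± 0.11, adjusted p = 0.079), Inhbb (0.05 ± 0.12, and 0.60 ± 0.24 on its other probe set), Atf4 (0.43 ± 0.15), Myc (0.80 ± 0.32), Fbxo30 (0.13 ± 0.13) and Havcr1 (-0.33 ± 0.16).

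Slow-fibre sarcomere genes rose in 5 of 14 members in untreated mutant muscle (median 0.70, 7 adjusted over the list alone), with the slow myosin Myh7 at 1.48 ± 0.36 and the troponin Tnnc1 at 1.03 ± 0.24. Oxidative phosphorylation genes fell in 14 of 37 (-0.24, 18 alone), such as Ndufs4 (-0.69 ± 0.16, but -0.28 and not called with the mean of its probe sets) and Cox7a1 (-0.64 ± 0.15), while ribosomal proteins rose in 10 of 20 (0.30, 12 alone), such as Rps19 (0.56 ± 0.11) and Rpl8 (0.54 ± 0.11). Clock genes rose in 5 of 17 (0.37, 8 alone), with Per2 at 1.98 ± 0.52 (1.12 with the mean of its probe sets) and Per1 at 1.76 ± 0.37. Autophagy genes were higher in 6 of 23 and lower in 1 (0.21, 8 and 2 alone), with Map1lc3b (lost in 10 of 26 settings) and Bnip3 both at 0.54. The adipocyte list had 2 of 18 higher (0.43, 2 alone), the lipid droplet protein Plin4 (1.68 ± 0.19) and the lipase Pnpla2 (1.07 ± 0.22, or 0.61 with the mean of its probe sets). Heat shock and immediate-early genes had 3 of 21 higher (0.54, 6 alone), with Btg2 at 1.15 ± 0.29 and Ier3 at 1.10 ± 0.26. Markers of macrophages were lower in 7 of 25 (-0.37, 7 alone), led by the antigen-presenting genes H2-Aa (-1.90 ± 0.33) and H2-Ab1 (-1.23 ± 0.27), and the call of the list was lost in 7 of 27 other settings. Its median was -0.02 with the actin covariate, -0.24, -0.18 and -0.78 without untreated mutant replicates 1, 2 and 4, and -0.30 without untreated wild-type replicate 2. Only the value without replicate 4 was called among these. With the 18S covariate it was -0.71 and called, so the covariates moved it in opposite directions. The NRF2 list had 3 of 17 higher and 1 lower (0.07, the same alone), with Gpx3 at 1.21 ± 0.23 and Gstm2 at 0.97 ± 0.16, and its call was lost under median centring and quantile normalization (adjusted p = 0.0537 and 0.0648) and in 11 of 27 other settings in all. Its median lay between 0.04 and 0.18 without single arrays, and was 0.22 and called with the 18S covariate. Heat shock genes were at 0.24 without untreated mutant replicate 1 and 0.31 without untreated wild-type replicate 2, clock genes at 0.21 without the latter, and autophagy genes at 0.32 without untreated mutant replicate 2. With the 18S and actin covariates the adipocyte list was at 0.69 and 0.71 and heat shock genes at 0.35 and 0.34. Slow-fibre genes were at 0.44 with the actin covariate and ribosomal proteins at 0.19 with the 18S covariate, and these lists stayed called. None of these 9 lists was called with an estimated correlation (adjusted p = 0.179 to 0.76 with an estimated correlation). Of the 14 lists camera called in this comparison, fry called all but the adipocyte, heat shock and macrophage lists.

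Over all genes 2840 were called between the genotypes in untreated muscle, 1232 higher and 1608 lower in mutants, and 558 changed at least 2-fold. Median centring gave 1595 higher and 1326 lower of 2921. Without untreated wild-type replicate 2 the count was 1649, and with the 18S control signal as a covariate, chosen after the data were seen, it was 1336. All 2840 genes kept their sign with it, their median absolute change went from 0.65 to 0.63 and their median standard error from 0.15 to 0.19. The 3 prime minus 5 prime signal of the actin control was 0.159 to 0.182 in untreated wild type and -0.0611 to 0.141 in untreated mutants. With it as a covariate, also chosen after the data were seen, 1348 genes were called. All 2840 kept their sign, the median absolute change was 0.59 and the median standard error 0.17. Fbxo32 (1.22, adjusted p = 0.24), Trim63 (0.75, adjusted p = 0.187), Lcn2 (1.93, adjusted p = 0.0998), Acvr2b (0.49, adjusted p = 0.161), Fst (-0.69, adjusted p = 0.0927), Id1 (1.06, adjusted p = 0.0652) and Ddit4 (2.57, adjusted p = 0.0646) were not called with it. Nor were Map1lc3b, Bnip3, Myh7, Tnnc1, Ndufs4, Cox7a1, Btg2, Ier3, Per2 and H2-Ab1, while Col1a1 was at -3.69 and called. In kidney this signal averaged 1.44 and 1.06 with no overlap of the arrays, and 7518 genes were called with it as a covariate.

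**Figure D2:**
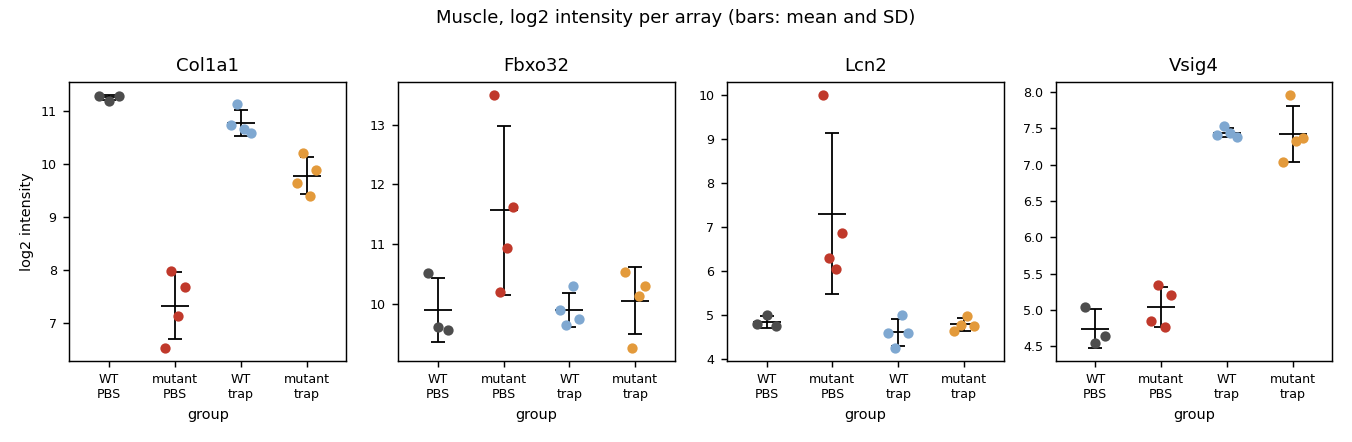
Log2 intensity of Col1a1, Fbxo32, Lcn2 and Vsig4 in each muscle array (points) for 4 groups, with bars for mean and SD. Col1a1 was at 11.25 in untreated wild type, 7.33 in untreated mutants and 9.77 in treated mutants, and 1 untreated mutant had the highest Fbxo32 and Lcn2.

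With the trap, Col1a1 and Col3a1 of mutant muscle were higher than under PBS. Col1a1 rose by 2.45 ± 0.25, to 9.77 ± 0.34 (n = 4 and 4, adjusted p = 0.000181), Col3a1 by 2.29 ± 0.31, Kera by 2.09 ± 0.25 and Aplnr 4.59-fold (1.31 on the log2 scale with the mean of its probe sets). Vsig4, a complement receptor of tissue macrophages, rose by 2.39 ± 0.18 on its 1 probe set. Retnla, a secreted protein of alternatively activated macrophages (2.28 ± 0.36), Tceal7 (2.18 ± 0.39) and Gamt, the last enzyme of creatine synthesis (2.02 ± 0.34), completed the 8 largest rises. Mss51, a mitochondrial gene of muscle, fell by 2.99 ± 0.56 and Lcn2 fell by 2.52 ± 0.58, to 4.79 ± 0.14. The other large falls were in Tmem100, Ovgp1, Avil, Ctxn3, Dnase1 and Cebpd (-1.85 to -1.66). Arrays did not overlap for these 16 genes, and adjusted p was at most 0.0246. In 3 of the 8 rises and 3 of the 8 falls the dimmer group lay at or under 5.52, as above. Without untreated mutant replicate 1 the change of Lcn2 was -1.62.

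Matrix genes rose in 14 of 31 members with the trap in mutant muscle (median 0.69, 19 adjusted over the list alone) and interferon response genes in 8 of 26 (0.40, 12 alone), with Iigp1 at 1.52 ± 0.42 (lost in 11 of 26 settings) and Cxcl9 at 1.49 ± 0.27 (0.91 with the mean of its probe sets). Glucocorticoid targets fell in 4 of 20 (-0.57, 7 alone), including Pik3r1 (-1.64 ± 0.27). The wasting list had 3 of 22 lower and 1 higher (-0.22, 7 and 1 alone), led by Fbxo31, a ubiquitin ligase subunit (-1.23 ± 0.20), and the transcription factor Foxo1 (-0.93 ± 0.25, lost in 12 of 26 settings). Fbxo32 was at 10.05 ± 0.55 against 11.57 ± 1.41 (-1.51 ± 0.50, n = 4 and 4, adjusted p = 0.085) and Trim63 at 11.47 ± 0.32 against 12.02 ± 0.73 (-0.55 ± 0.27, adjusted p = 0.253), and neither was called. Without untreated mutant replicate 1 they were at -0.87 and -0.19. Macrophage markers rose in 5 of 25 (0.59, 11 alone), with H2-Aa at 1.34 ± 0.31 and the chemokine Ccl6 at 1.16 ± 0.32 (lost in 15 of 26 settings). The macrophage median was 0.91 with the 18S covariate and 0.27 with the actin covariate, called with both. None of these 5 lists was called with an estimated correlation: adjusted p = 0.491 for matrix and interferon response, 0.499 for glucocorticoid targets, 0.563 for wasting and 0.634 for macrophages with an estimated correlation.

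Smaller shifts with the trap in mutant muscle were called in ribosomal proteins (median -0.18, 2 of 20 lower, Rps27 -0.44 ± 0.12, lost in 17 of 26 settings, and Rpl8 -0.42 ± 0.10, lost in 10 of 26), autophagy genes (-0.24, 2 of 23 lower, Gabarap, lost in 11 of 26 settings, and Pik3c3, and 2 higher) and slow-fibre genes (-0.41, 1 of 14 lower, Myoz2 -0.76 ± 0.16). Clock genes had a median of -0.24 with 1 of 17 lower, Cry2 (-0.90 ± 0.25, lost in 18 of 26 settings), and lymphocyte markers a median of 0.30 with 1 of 18 higher, the immunoglobulin gene Ighm (1.31 ± 0.32, but 0.15 and not called with the mean of its probe sets). The calls of the clock and lymphocyte lists were lost in 7 of 27 and 7 of 26 settings. The clock list was not called without untreated mutant replicate 1 or 4. The lymphocyte list was not called without untreated mutant replicate 4 (0.26) or treated mutant replicate 2 (0.10). The autophagy list was at -0.15 without untreated mutant replicate 1. With the 18S covariate 4 of the 10 calls ended: ribosomal proteins (-0.06, adjusted p = 0.1), slow-fibre (-0.19, adjusted p = 0.0784), clock (-0.12, adjusted p = 0.412) and lymphocyte genes (0.11, adjusted p = 0.583). The autophagy list stayed called at -0.16. With the actin covariate the clock (-0.17) and lymphocyte (0.22) calls ended, and the slow-fibre list was at -0.19 and called. Adjusted over the list alone, 6, 6, 3, 1 and 1 members moved in the direction of the list. Of the 10 lists called, none was called with an estimated correlation (adjusted p = 0.491 to 0.712 with an estimated correlation). Kif3a, Inhba, Inhbb, Fst, Acvr2b, Fbxo30, Havcr1, Id1, Atf4 and Myc were not called, with changes from -0.53 to 0.15.

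The trap was associated with 1125 called genes in mutant muscle, 743 higher and 382 lower, of which 190 changed at least 2-fold. The 18S control signal averaged 11.7 in untreated and 12.3 in treated mutant muscle (difference 0.59, exact permutation p = 0.0571, two-sided, 4 against 4). In wild type the difference was 0.12 (exact permutation p = 0.514, 4 against 3). The mean of both was 0.36 (exact permutation p = 0.0286, labels exchanged within each genotype). With it as a covariate 127 genes were called. All 1125 kept their sign, their median absolute change went from 0.66 to 0.59 and their median standard error from 0.15 to 0.19. Mss51 went to -1.89 (adjusted p = 0.22) and Lcn2 to -2.37 (adjusted p = 0.223), and neither was called. With the actin covariate 236 genes were called, all 1125 kept their sign, the median absolute change was 0.59 and the median standard error 0.16. Lcn2 was at -2.06 (adjusted p = 0.125) and not called with it. The count was 554 without untreated mutant replicate 1, 2140 without untreated mutant replicate 2, and 629, 687 and 597 without treated mutant replicates 2, 3 and 4.

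In wild-type muscle 11 genes were called with the trap, and 130 with array weights. Vsig4 rose by 2.70 ± 0.19, from 4.74 ± 0.27 to 7.44 ± 0.06 (n = 3 and 4, adjusted p = 3.8e-06), and Mss51 fell by 4.70 ± 0.60 (adjusted p = 0.00477). Dmp1, a matrix phosphoprotein of bone (2.50 ± 0.30), Ak4, a mitochondrial adenylate kinase (1.68 ± 0.24), Acer2, a ceramidase (1.26 ± 0.21), and Gadd45a, a growth-arrest gene (1.00 ± 0.15), rose too, and Slc30a2, a zinc transporter (-1.96 ± 0.32), Junos, Ccdc3 and H1f8 fell. The call of Ccdc3 was lost in 12 of 26 settings and that of Acer2 in 10 of 26. With the mean of all probe sets Ak4 was at 0.97 and called and Acer2 at 0.68 and not called. Of the 11 genes 6 were higher and 5 lower, and 2068 had an unadjusted p under 0.05. With the actin covariate 6 were called, and 29 with only the 2 groups fitted. In 5 of the 10 largest changes the dimmer group lay at or under 5.52, and H1f8 did in both groups. Without single arrays the count was 7, 31 and 6 (treated wild-type replicates 1, 2 and 4), 1, 1 and 5 (untreated wild-type replicates 1, 2 and 3) and 22 (untreated mutant replicate 2). Camera called 10 lists, led by macrophage markers (median 0.71, 0 of 25 called over all genes and 10 over the list alone), and 0 with an estimated correlation (adjusted p = 0.614 for macrophage markers and 0.536 to 0.751 for the others with an estimated correlation).

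Under the trap, mutant muscle still had lower matrix genes than wild type, in 14 of 31 members (median -0.80, 27 adjusted over the list alone, adjusted p = 0.0657 with an estimated correlation). Col8a1, a network-forming collagen, was lower by -1.80 ± 0.26 (-1.05 with the mean of its probe sets), and Serpinb1a, a protease inhibitor (-2.51 ± 0.39), Cks2, a cell cycle protein (-2.13 ± 0.46), Dmp1 (-1.83 ± 0.28) and the tubulin Tubb2b (-1.63 ± 0.36) were the other large differences (n = 4 and 4, adjusted p at most 0.032). In 6 of the 10 largest differences the dimmer group lay at or under 5.52, and Apoc3 did in both groups, so the sizes for these genes are uncertain. Higher in mutants were Acsm3 (1.63 ± 0.33), the glucocorticoid-induced Fkbp5 (1.43 ± 0.34, lost in 15 of 26 settings), Tfcp2l1, Apoc3 and Fbp2, a muscle fructose bisphosphatase (1.06 ± 0.15). Cell cycle genes had a median of -0.90 (0 of 31 called over all genes and 22 lower adjusted over the list alone), and of 16 lists called by camera none was called with an estimated correlation (adjusted p = 0.0657 to 0.577 with an estimated correlation). In all 295 genes were called, 26 higher and 269 lower. With the actin covariate 34 were called, all 295 kept their sign, the median absolute change went from 0.78 to 0.74 and the median standard error from 0.16 to 0.19. The count was 177, 101 and 127 without treated mutant replicates 1, 3 and 4, and 106, 166 and 108 without treated wild-type replicates 1, 2 and 4.

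The change with the trap differed between the genotypes in muscle for single genes, among them Kera, Col1a1 and Tnmd. The interaction was 3.01 ± 0.36 for Kera, 2.93 ± 0.36 for Col1a1, 2.56 ± 0.36 for Tnmd, 2.41 ± 0.38 for Wif1 and 2.32 ± 0.43 for Alas2, the erythroid enzyme of haem synthesis, lost in 15 of 25 settings (adjusted p at most 0.0425, arrays 4, 4, 4 and 3). Kera, Wif1 and Alas2 lay under 5.52 in untreated mutants, so the sizes for them are uncertain. It was negative for Ctps2, an enzyme of CTP synthesis (-1.56 ± 0.27, but -0.82 and not called with the mean of its probe sets, lost in 10 of 25 settings), Ahnak (-1.04 ± 0.19, but 0.05 with the mean of its probe sets, lost in 11 of 25 settings) and the phosphatase Ptp4a3 (-0.90 ± 0.17, lost in 17 of 25 settings). Camera called 18 lists, among them matrix (median 0.73, 3 of 31 higher and 16 adjusted over the list alone) and glucocorticoid targets (-0.82, 0 of 20 and 9 lower alone), and 0 with an estimated correlation (adjusted p = 0.344 to 0.777 with an estimated correlation). In all 30 genes were called, 27 higher and 3 lower, and 35 higher and 10 lower under median centring. The count was 570 without untreated mutant replicate 2, 53 and 13 without treated mutant replicates 1 and 3, 13 without treated mutant replicate 4, 16, 16 and 17 without treated wild-type replicates 1, 3 and 4, and 12 and 14 without untreated wild-type replicates 2 and 3.

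Treated mutants still differed from untreated wild type in muscle. Vsig4 was higher by 2.69 ± 0.19, Sln, the calcium pump regulator sarcolipin, by 2.80 ± 0.57, Acsm3 by 1.81 ± 0.35, Acer2 by 1.70 ± 0.21 and Ak4 by 1.65 ± 0.24. Mss51 (-4.10 ± 0.60), Kera (-2.47 ± 0.27), Wif1 (-2.18 ± 0.28), Col4a5 (-2.12 ± 0.21), Ecrg4 (-2.04 ± 0.21) and Fst (-0.97 ± 0.20, lost in 13 of 26 settings) were lower (n = 4 and 3, adjusted p at most 0.0313). The mean of all probe sets gave 1.73 for Sln, 0.88 for Acer2 and 1.03 for Ak4, still called. In 3 of the 10 largest differences the dimmer group lay at or under 5.52. Matrix genes were lower in 13 of 31 members (median -0.84, 25 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation), and fibroblast, pericyte and smooth muscle markers in 3 of 18 (-0.63, 12 alone, adjusted p = 0.047 with an estimated correlation). Camera called 14 further lists that were not called with an estimated correlation (adjusted p = 0.0988 to 0.841 with an estimated correlation). In all 173 genes were called, 26 higher and 147 lower. The count was 111 without treated mutant replicate 1 and 106, 81 and 53 without untreated wild-type replicates 1, 2 and 3.

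In mutant kidneys, Slc22a19, Slc22a30 and Havcr1 were higher with the trap. Slc22a19 rose by 4.33 ± 0.30, from 5.09 ± 0.82 to 9.42 ± 0.33 (n = 4 and 4, adjusted p = 2.72e-06), and Slc22a30 by 2.92 ± 0.33, against 11.46 ± 0.23 and 11.66 ± 0.05 in untreated wild type. Havcr1 rose by 3.22 ± 0.33, to 11.66 ± 0.73, and by 2.89 on its other probe set. The metabolic genes Akr1c14 (3.10 ± 0.65), Ugt2b37 (2.83 ± 0.65) and Akr1d1 (2.57 ± 0.39), Vsig4 (2.60 ± 0.24) and the interferon-induced Ifi27l2a (2.40 ± 0.43) completed the largest rises. The falls were led by Npy6r, a receptor of the neuropeptide Y family (-2.19 ± 0.23), Reln, the matrix protein reelin (-1.78 ± 0.12, or -0.89 with the mean of its probe sets), Gpr34 (-1.69 ± 0.26), the tetraspanin Tspan1 (-1.55 ± 0.17) and P2ry14, a receptor for UDP-glucose (-1.51 ± 0.11). H60c, Dmrt2 and the metalloproteinase Mmp7 followed (-1.47 to -1.32). Arrays did not overlap for these 16 genes. In 4 of the 8 rises and 3 of the 8 falls the dimmer group lay at or under 5.07, so these changes may be understated and their order is no ranking.

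Proximal tubule genes rose in 5 of 29 members with the trap in mutant kidneys (median 0.82, 19 adjusted over the list alone), among them Miox, an inositol oxygenase (1.86 ± 0.38). Collecting duct genes fell in 8 of 23 (-0.50, 14 alone), led by Foxi1, the regulator of intercalated cells (-1.30 ± 0.19), and the potassium channel subunit Kcne1 (-1.18 ± 0.19). Interferon response genes rose in 5 of 26 (0.50, 12 alone), with the chemokines Cxcl9 (1.24 ± 0.31, lost in 15 of 25 settings) and Cxcl10 (1.08 ± 0.22), and complement genes in 4 of 19 (0.28, 6 higher and 1 lower alone), with Cfi (1.31 ± 0.31, lost in 10 of 26 settings) and Fgg (1.13 ± 0.28, lost in 11 of 26). Loop and distal tubule genes rose in 3 of 16 (0.18, 3 alone), with Egf at 2.37 ± 0.55 and Slc12a3 at 1.47 ± 0.18. The cell cycle list had 1 of 31 higher, Kif11 (0.60 ± 0.12, list median 0.51, 16 alone), the fatty acid oxidation list 1 of 24, Fabp3 (1.18 ± 0.23, list median 0.30, 8 alone), and the cholesterol list 1 of 18, Cyp51 (1.16 ± 0.20, list median 0.23, 3 higher and 1 lower alone). Adipocyte markers had a median of 1.04 with 0 of 18 called over all genes and 4 over the list alone. None of these 9 lists was called with an estimated correlation: adjusted p = 0.154 for collecting duct, 0.221 for proximal tubule and complement, 0.269 for interferon response, 0.357 for cell cycle, 0.425 for fatty acid oxidation and loop, 0.486 for cholesterol and 0.549 for adipocytes with an estimated correlation. With the 18S covariate the complement (0.29, adjusted p = 0.227) and loop lists (0.15, adjusted p = 0.145) were not called, while the adipocyte (2.73), fatty acid oxidation (0.67), cholesterol (0.59) and collecting duct lists (-0.76) lay farther from 0 and stayed called. The median of the adipocyte list was 0.56 and that of fatty acid oxidation 0.18 without treated mutant replicate 1. That of the loop list was 0.11 without treated mutant replicate 3. The cholesterol list was at 0.49 and 0.14 without untreated mutant replicates 2 and 3, and at 0.17 and not called without treated mutant replicate 2.

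Camera also called oxidative phosphorylation (median 0.18), lymphocyte (0.14), endothelial (0.25), hypoxia (0.25), chaperone (0.18), glycolysis (0.15), p53 (-0.28) and ribosomal protein lists (-0.10), each with 0 members past the threshold of limma over all genes. Adjusted over the list alone, 3 members of the p53 list, 2 of the lymphocyte list and 1 each of the hypoxia and endothelial lists passed. The call was lost in 10 of 27 settings for hypoxia and in 9 of 27 for glycolysis and for chaperones. With the 18S covariate 11 of the 17 calls stood and those of complement, loop, hypoxia, chaperones, endothelial and lymphocyte genes ended. The lists called went from 14 higher and 3 lower to 8 higher and 11 lower. Oxidative phosphorylation was at 0.35 and glycolysis at 0.33 with the covariate, both still called. The medians were 0.08 for chaperones and 0.14 for endothelial genes with it, 0.28, 0.10 and 0.11 for chaperones without treated mutant replicates 1 and 2 and untreated mutant replicate 4, 0.08 for glycolysis without treated mutant replicate 2 and 0.07 for lymphocytes without untreated mutant replicate 4. Of the 17 lists called in mutant kidneys with the trap, 0 were called with an estimated correlation (adjusted p = 0.154 for collecting duct, 0.221 for proximal tubule and 0.221 to 0.737 for the rest with an estimated correlation). Inhba (0.08 ± 0.12), Inhbb (0.23 ± 0.27), Fst (-0.12 ± 0.17), Lcn2 (-0.46 ± 0.21), Trim63 (0.67 ± 0.36), Fbxo32 (-0.55 ± 0.30), Myc, Atf4, Id1, Acvr2b, Fbxo30 and Kif3a were not called.

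In mutant kidneys 427 genes were called with the trap, 191 higher and 236 lower, and 98 changed at least 2-fold. The 18S control was lower in treated kidneys, 10.3 to 11.6 against 11.8 to 12.6 (-1.37 in mutants and -0.62 in wild type, exact permutation p = 0.000408 for the mean of both, two-sided, with labels exchanged within each genotype of 8 and 7 arrays), and with it as a covariate 1 gene was called. It follows the treatment, so the median standard error of the 427 genes went from 0.14 to 0.29 while their median absolute change went from 0.71 to 0.74. The count was 216, 771 and 179 without untreated mutant replicates 1, 2 and 4, and 230 without treated mutant replicate 2.

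In wild-type kidneys the trap was associated with lower expression of cell cycle genes, in 12 of 31 members (median -0.76, 27 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation). Esco2, a cohesin acetyltransferase of S phase, fell by 1.96 ± 0.26 and Pbk, a mitotic kinase, fell by 1.75 ± 0.26 (n = 3 and 4, adjusted p = 0.00502 and 0.00763). Esco2 lay under 5.07 in both groups and Ces1g in the treated group, so the sizes for them are uncertain. Ces1g, a carboxylesterase (-3.23 ± 0.22), Bcat1, a branched-chain aminotransferase (-2.38 ± 0.52, lost in 16 of 26 settings), and the calcium-binding parvalbumin gene Pvalb (-1.64 ± 0.21) fell as well. Havcr1 rose by 1.73 ± 0.36 (adjusted p = 0.0336, lost in 9 of 26 settings), as did Gadd45g (2.11 ± 0.29), Ly6f (1.73 ± 0.34), Cebpd (1.72 ± 0.24) and Kynu, an enzyme of tryptophan breakdown (1.69 ± 0.37, but 0.96 and not called with the mean of its probe sets, and lost in 16 of 26 settings). Limma called 156 genes, 58 higher and 98 lower, and 2 with the 18S covariate. All 156 kept their sign with it, while the median absolute change went from 0.91 to 0.82 and the median standard error from 0.17 to 0.21. Without single arrays the count was 408, 96 and 46 (treated wild-type replicates 1, 3 and 4) and 24, 34 and 56 (untreated wild-type replicates 1, 2 and 3). It was 20 with only the 2 groups fitted, 53 with the replicate number as a block and 580 with array weights. Treated wild-type replicate 1 had Slco1a1 at 10.9, where the other 3 had 5.93 to 6.50. Camera called 17 lists and 0 with an estimated correlation (adjusted p = 0.288 to 0.803 with an estimated correlation).

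Genotype differences in kidney were wide under the trap as well. Lcn2 was higher in treated mutants by 8.06 ± 0.21, and Sprr2f, Serpina10, Lgi2 and Socs3 by 4.43 to 5.17, while Cyp2d12 (-4.99 ± 0.18), Dnase1 (-4.24 ± 0.41), Hpd, an enzyme of tyrosine breakdown (-4.11 ± 0.47), Slc22a7 (-3.82 ± 0.22) and Slc22a22 (-3.75 ± 0.52) were lower (n = 4 and 4). In 4 of these 10 the dimmer group lay at or under 5.07. Inhba (1.22 ± 0.12), Inhbb (3.99 ± 0.27), Fst (1.63 ± 0.17), Myc (1.73 ± 0.19), Havcr1 (1.52 ± 0.33) and Fbxo32 (1.04 ± 0.30) were higher and Trim63 (-2.09 ± 0.36) and Acvr2b (-0.45 ± 0.13) lower. The mean of all probe sets gave 2.03 for Inhbb, still called, and 0.56 for Fbxo32, not called. Limma called 8252 genes, 3944 higher and 4308 lower (3209 and 6959 under median centring). Tubule injury and complement lists were called with an estimated correlation too (both adjusted p = 0.0372 with an estimated correlation, 23 of 23 higher and 14 of 19 higher with 1 lower, and 23 and 16 higher adjusted over the list alone). The other 18 lists called by camera were not (adjusted p = 0.12 to 0.524 with an estimated correlation).

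The kidney response to the trap differed between genotypes for single tubule genes. The interaction was 3.80 ± 0.44 for Slc22a19, 3.54 ± 0.49 for Slc22a30, 3.11 ± 0.30 for Ces1g, 2.85 ± 0.35 for Esco2 and 2.80 ± 0.62 for Ugt2b38, the last lost in 12 of 25 settings, and it was -2.05 ± 0.28 for Foxi1, -2.04 ± 0.42 for the kinase gene Sgk1, -2.03 ± 0.17 for P2ry14, -1.76 ± 0.40 for Gadd45g, lost in 11 of 25 settings, and -1.66 ± 0.18 for Dmrt2 (adjusted p at most 0.0427, arrays 4, 4, 4 and 3). Untreated mutants had Slc22a30 at 4.65 and Slc22a19 at 5.09, at about the 5.07 given above for fast-fibre genes in kidney, Ces1g lay under it in 3 groups and Esco2 in all 4. The sizes for these genes are therefore uncertain and their order is no ranking. Collecting duct genes had a lower interaction in 10 of 23 members (median -1.04, 16 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation), and 14 further lists called by camera were not called that way (adjusted p = 0.0989 to 0.894 with an estimated correlation). Limma called 246 genes, 118 higher and 128 lower, and 145 with the 18S covariate. All 246 kept their sign with it, while the median absolute change went from 1.13 to 1.16 and the median standard error from 0.22 to 0.26. Without single arrays the count was 496 and 146 (treated wild-type replicates 1 and 4), 160, 459 and 127 (untreated mutant replicates 1, 2 and 4), 96, 128 and 147 (untreated wild-type replicates 1, 2 and 3) and 131 (treated mutant replicate 4).

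Treated mutant kidneys differed from untreated wild type in 8425 genes, 3933 higher and 4492 lower (3298 and 6780 under median centring, and 2713 in all with the 18S covariate). With that covariate 8322 of the 8425 kept their sign, while the median absolute change went from 0.62 to 0.53 and the median standard error from 0.13 to 0.23. Lcn2 was higher by 7.66 ± 0.23, Havcr1 by 3.25 ± 0.36, Inhba by 1.62 ± 0.12, Inhbb by 3.54 ± 0.29, Fst by 1.36 ± 0.18 and Myc by 2.08 ± 0.21, and Sprr2f, Col12a1, Serpina10 and Lgi2 by 4.77 to 5.27 (n = 4 and 3). Fbxo32 (1.35 ± 0.33), Atf4 (0.68 ± 0.13) and Id1 (0.73 ± 0.28, adjusted p = 0.0411, not called under median centring) were higher too. The mean of all probe sets gave 2.40 for Col12a1, 1.84 for Inhbb and 0.79 for Fbxo32, still called. Slco1a1 (-5.53 ± 0.82), Pzp, a protease inhibitor (-4.61 ± 0.66), Slc7a13, an amino acid transporter (-4.58 ± 0.53), Dpys (-4.23 ± 0.25), Pvalb (-4.17 ± 0.21) and Trim63 (-2.62 ± 0.39) were lower. In 5 of the 10 largest differences the dimmer group lay at or under 5.07. Tubule injury genes were higher in 23 of 23 members (median 2.66) and complement genes in 15 of 19 with 1 lower (2.71), with the same counts adjusted over the list alone and adjusted p = 0.0338 and 0.032 with an estimated correlation. The other 19 lists called by camera were not (adjusted p = 0.111 to 0.556 with an estimated correlation).

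**Figure D3:**
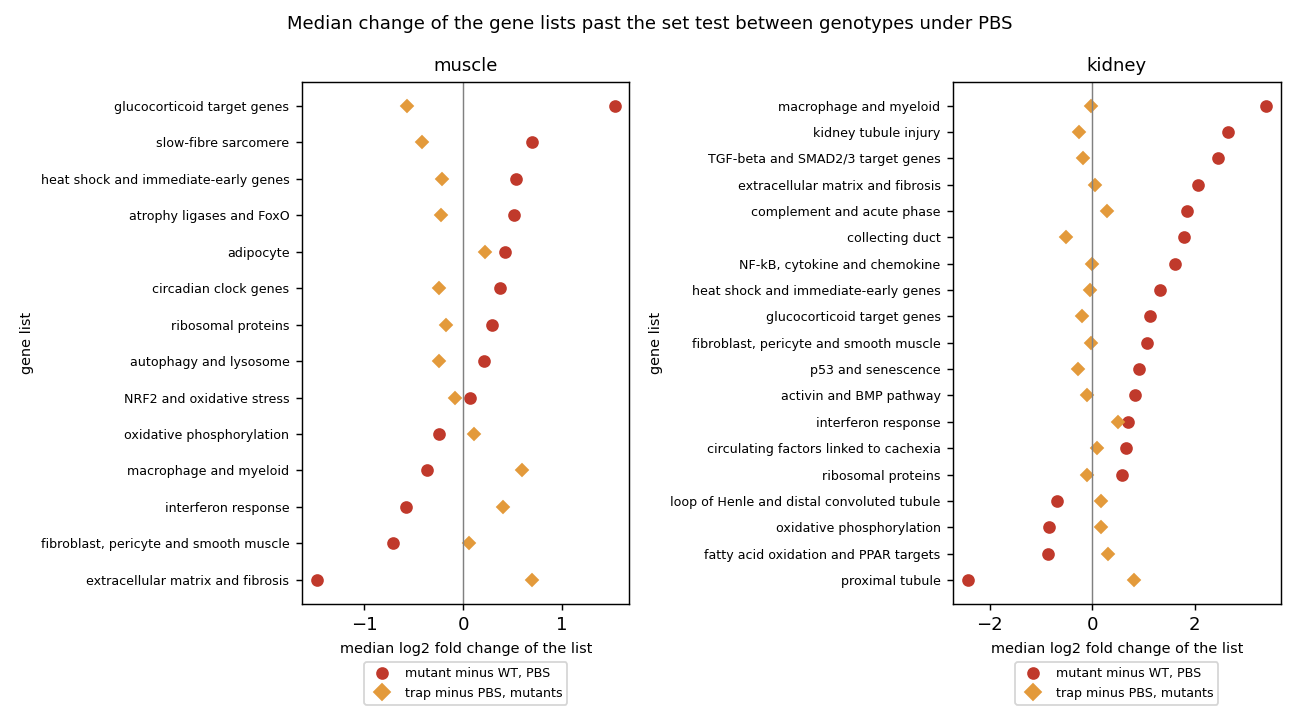
Median log2 fold change of the gene lists called by camera between genotypes under PBS (circles), in muscle (14 lists) and kidney (19 lists), with the median change with the trap in mutants (diamonds) beside it. In muscle the matrix list was at -1.48 and then 0.69, and in kidney the proximal tubule list was at -2.42 and then 0.82.

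Genotype effects under PBS and under the trap share no arrays. Across genes, which are not independent replicates, their fold changes correlated at r = 0.52 in muscle (covariance 0.0549, slope 0.31) and r = 0.91 in kidney (covariance 0.528, slope 0.74). Simulated unchanged groups gave r from -0.54 to 0.61 and covariances from -0.0162 to 0.0195 in muscle, and r from -0.63 to 0.63 and covariances from -0.0146 to 0.0154 in kidney. In muscle r thus lay inside the simulated range and only the covariance outside it, while in kidney both lay outside. Of the genes called under PBS, 86.5% in muscle and 97.4% in kidney had the same sign under the trap, and no simulated share was computed for this. In muscle, 221 of the 269 genes lower under the trap were also lower under PBS, where independent lists would share 24.3.

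Genotype under PBS and the trap in mutants share the 4 untreated mutant arrays, so their fold changes correlate below 0 with no effect at all. In muscle r was -0.79, inside the range of simulated unchanged groups (-0.84 to 0.19, mean -0.41), while the covariance of -0.101 lay outside theirs (-0.0426 to 0.00351). In kidney r was -0.53, also inside the simulated range (-0.81 to 0.43, mean -0.42), and the covariance of -0.124 lay outside (-0.0361 to 0.00995). With the 4 shared arrays split into 2 and 2 r lay between -0.61 and -0.53 in muscle and between -0.56 and -0.34 in kidney. In muscle 586 of the 743 genes that rose with the trap were lower in untreated mutants, among them Col1a1 and Kera (67.2 expected of independent lists), and 316 of the 382 that fell were higher (26.5 expected). In kidney the corresponding counts were 139 of 191 (51.1 expected) and 215 of 236 (58.7 expected). These counts carry the shared arrays and independence is no fair comparison for them. With the untreated mutants split into 2 and 2, in 6 ways, muscle had 80 to 316 shared genes that rose with the trap (8.64 to 51 expected) and 16 to 194 that fell (1.54 to 19.4 expected). Kidney had 15 to 320 (5.99 to 78.6 expected) and 29 to 270 (8.02 to 72.1 expected), and in all 6 splits of each the shared number was above the expected one. The trap effects in mutants and in wild type, which share no arrays, correlated across genes at 0.17 in muscle and 0.06 in kidney. Both lay inside the ranges of simulated unchanged groups (-0.78 to 0.65 and -0.70 to 0.65), which are too wide to tell a weak relation from none. Among called genes, 4 of the 6 that rose in wild-type muscle rose in mutants too (0.251 expected of independent lists) and 1 of the 5 that fell also fell (0.107 expected). In kidney 8 of the 58 that rose in wild type rose in mutants (0.623 expected) and 4 of the 98 that fell also fell (1.30 expected). In the opposite direction kidney shared 2 and 1 genes (0.77 and 1.05 expected) and muscle 0.

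Kidney and muscle of untreated mutants moved apart for Col1a1 and Col3a1. The genotype effect was greater in kidney than in muscle by 6.72 ± 0.50 for Col1a1 and 5.53 ± 0.44 for Col3a1 (adjusted p = 3.62e-11 and 1.35e-10, 7 animals under PBS), 5.66 ± 0.69 for Lcn2, 2.23 ± 0.28 for Fst, 1.84 ± 0.16 for Inhba and 1.30 ± 0.39 for Myc, and it was -4.23 ± 0.50 for Trim63. The fit with the animal as a block called 6609 genes, 3502 with a higher and 3107 with a lower effect in kidney than in muscle. Of the genes lower in muscle, 649 were higher in kidney (399.7 expected of independent lists) and 456 lower (429.9 expected). Of those higher in muscle 489 were higher in kidney (306.2 expected) and 214 lower (329.4 expected). Genes called in muscle in either direction were thus found among those higher in kidney more often than expected. Untreated wild-type muscle had Lcn2 at 4.85, under the 5.52 given above, and the muscle change was 1.56 without untreated mutant replicate 1 against 2.46 with it, so the size of its tissue difference is uncertain. Col1a1 and Col3a1 were chosen here after their values were seen.

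Across the 8 mutant animals, kidney Inhba showed no detectable relation to the mean of the wasting list in muscle (Pearson r = 0.01, Spearman rho = 0.21, exact permutation p = 0.978 and 0.619), nor was the kidney injury list (r = 0.21, rho = -0.05, exact permutation p = 0.572 and 0.935). Residuals from the group means over all 15 animals gave r = 0.02 and rho = -0.03 for Inhba (permutation p = 0.949 and 0.934) and r = 0.27 and rho = 0.26 for the injury list (permutation p = 0.319 and 0.341). After adjustment over the 4 relations p was 0.978 for each r and 0.935 for each rho. Without the 2 animals farthest from the median of the kidney measure r was 0.29, 0.61, -0.04 and 0.56 for Inhba and injury in mutants and for Inhba and injury in residuals, the last with a permutation p of 0.0474 before adjustment.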

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

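Predictions for 20 of the tests in this part were written before their result was seen. Those on connective tissue of every kind, fewer fibroblasts, array processing in kidney, macrophages, Vsig4 beside the 18S control and matrix genes beside the actin control were written after the result was seen. Single arrays far from the rest of their group were marked with Dixon's test at 95%. It was applied to 126 groups of 4 arrays, where chance alone marks about 5% of groups, and it marked 4.

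Kif3a in muscle was at 7.72 in treated wild-type replicate 2 and at 7.37 to 7.42 in the other 3. In kidney, Fst was at 8.75 in treated mutant replicate 3 (others 7.92 to 7.98), Fbxo30 at 6.42 in treated wild-type replicate 2 (7.31 to 7.37), and the mean of the glucocorticoid targets at 10.2 in treated wild-type replicate 4 (9.16 to 9.33).

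Differences between groups in the same effect, each by a test of the difference itself, marked the 30 genes of the genotype and trap interaction in muscle, the 246 genes in kidney and the 6609 genes whose genotype effect differed between the tissues. Among the latter were Inhba (1.84), Fst (2.23), Trim63 (-4.23), Lcn2 (5.66) and Myc (1.30). A signal outside the gene measurements marked the 18S ribosomal RNA control, lower by -1.01 in treated than in untreated kidneys.

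The fall of matrix genes in untreated mutant muscle (median -1.48) was weighed against several explanations. Others, such as the amount of tendon in a sample, were not tested. A single severely affected animal was excluded as the whole cause, since the median was -1.24 without untreated mutant replicate 1, and so was RNA quality as read by the 18S control (median -1.68 with it as covariate) or by the actin control (median -1.41 with its 3 prime minus 5 prime signal as covariate). An equal fall of all connective tissue markers, vessels included, was not seen. The mean of the matrix genes fell further than that of the other markers by -0.83 (95% interval -1.05 to -0.61). Those other markers fell as well (-0.69, 95% interval -0.94 to -0.44). Different markers need not fall equally with the same loss, so a loss of connective tissue of every kind is not excluded. Fewer fibroblasts and lower matrix expression in each cannot be told apart, with a difference of -0.13 (-0.48 to 0.21) from Pdgfra, Thy1, Pi16, Dpt and Gli1, a subset set after the values were seen. Both comparisons of markers were run and are given here.

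The rise of proximal tubule genes against collecting duct genes with the trap in mutant kidneys (difference of list means 1.52, 95% interval 0.93 to 2.10) was weighed against array processing that differed with treatment. Had it followed the 18S control in proportion and alike in both genotypes, wild-type kidneys would have shown 0.69. They showed -0.56 (-1.20 to 0.07), which argues against that account as the whole cause only if those conditions hold. These conditions were not tested, and the 0.69 carries no error. The 18S control was also lower in all treated than in all untreated kidneys, so the account is not excluded. One outlying animal was excluded, since the lowest difference with an array left out was 1.24. With the 18S covariate the difference was 1.74 (0.47 to 3.00).

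Vsig4 rose with the trap in muscle of mutants (2.39) and wild type (2.70) and in kidney of mutants (2.60) and wild type (1.17), the last chosen after its value was seen. An equal rise of all macrophage markers was excluded as the whole cause in muscle and mutant kidney, since the other markers had medians of at most 0.71 (quartiles 0.42 to 0.83). In muscle these markers did rise, with medians of 0.59 in mutants and 0.71 in wild type. A gain of only those macrophages that carry Vsig4 was not tested and stays open. In wild-type kidney the median of the markers was 0.45 (0.18 to 0.60) and the accounts cannot be told apart. With the 18S covariate Vsig4 stayed called in mutant muscle (2.35). In kidney the call ended, from 2.60 ± 0.24 to 2.18 ± 0.49 in mutants and from 1.17 ± 0.26 to 0.98 ± 0.32 in wild type, since the covariate follows the treatment and widens the error, so the account stays open there.

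Group labels were reassigned over the arrays of each comparison. With 35 splits the smallest share possible is 1 of 35, and the shares were not adjusted over the counts. Chance is thus not excluded for any 1 count. It was called unlikely where few splits reached the real count. Only the real split did in 1 of 35 for muscle genotype under PBS (2840, highest other 2680), trap in mutants (1125, 14), genotype under trap (295, 3) and treated mutants against untreated wild type (173, 5). The same held in 1 of 35 for kidney genotype under PBS (9174, 6863), trap in mutants (427, 39), genotype under trap (8252, 2) and treated mutants against untreated wild type (8425, 5834), for the tissue difference (6609, 4261), and in 1 of 100 for the kidney interaction (246, 34). For the muscle interaction 2 of 100 did (30, 117), and the other of these splits had several times the real count. Chance is therefore not called unlikely for this count. That split points to a structure of the samples that was not tested and for which the labels name no batch. For genotype under PBS the highest other split in both tissues grouped untreated mutant replicate 2 with the untreated wild-type arrays. It thus lay close to the real one. Chance was not called unlikely for the trap in wild type, with 2 of 35 in muscle (11, 17) and 2 of 35 in kidney (156, 357). Nor was it for the number of lists called, with 11 of 35 (14, 23) and 28 of 35 (10, 18) in muscle for genotype and trap in mutants, and 16 of 35 (19, 26) and 5 of 35 (17, 20) in kidney. For the trap in wild type, the split above the real one moved only 1 treated array to the 3 untreated ones. It was replicate 1 in kidney and replicate 2 in muscle, and without it the counts were 408 and 31. That kidney array had Slco1a1 at 10.9, near untreated wild type (10.7 to 11.1), against 5.93 to 6.50 in the other treated ones. These splits are thus close to the real one, and 1 unlike treated array is not told apart from chance. The sex of the animals entered no fit and was not checked, so it is not told apart as a source of such an array either.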

How the results depend on the processing

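All settings but the 18S and actin covariates, which were chosen after seeing the data, were chosen before the data were examined. The cause of a moved value was not tested unless it is given.

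Genes called in muscle interaction went from 30 to 48 with a trended prior variance and 65 with quantile normalization. Array weights gave 1881 for trap in mutants, 130 for trap in wild type, 996 for genotype under trap, 363 for the interaction and 341 for treated mutants against untreated wild type in muscle, and 580 for trap in wild type and 643 for the interaction in kidney. Fitting only the 2 groups compared, with fewer arrays, gave 1643 for genotype under PBS, 322 for trap in mutants and 29 for trap in wild type in muscle, and 226 and 20 for trap in mutants and wild type in kidney. A 2-fold minimum left, by construction, 558, 190, 61 and 77 in muscle (genotype under PBS, trap in mutants, genotype under trap, treated mutants), 2716, 98, 63, 1977, 160 and 2189 in kidney (genotype under PBS, trap in mutants, trap in wild type, genotype under trap, interaction, treated mutants) and 3081 for the tissue difference. The 18S covariate gave 1336, 127 and 12 in muscle (genotype under PBS, trap in mutants, interaction) and 1, 2, 145 and 2713 in kidney (trap in mutants, trap in wild type, interaction, treated mutants). The actin covariate gave 1348, 236, 6 and 34 in muscle (genotype under PBS, trap in mutants, trap in wild type, genotype under trap).

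An estimated correlation left 0 lists called of 14 and 10 in muscle and 0 of 19 and 17 in kidney (genotype under PBS, trap in mutants), and fry called 4 for trap in mutants in each tissue, 3 of them among the 10 in muscle and all 4 among the 17 in kidney. For genotype under PBS fry called 18 lists in muscle and 28 in kidney. The relation of kidney injury to the wasting list in residuals was 0.56 without the 2 farthest animals. Ahnak in the muscle interaction turned from -1.04 to 0.054 with the mean of all probe sets.

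Leaving out each array in turn gave 1649 to 3608 genes for genotype under PBS, 554 to 2140 for trap in mutants, 1 to 31 for trap in wild type, 101 to 382 for genotype under trap, 12 to 570 for the interaction and 53 to 233 for treated mutants in muscle. In kidney it gave 7766 to 9811, 179 to 771, 24 to 408, 7159 to 8486, 96 to 496 and 6841 to 9183 in the same order, and 5610 to 6340 for the tissue difference. Lists called were 13 to 17 and 9 to 14 in muscle and 19 to 21 and 14 to 20 in kidney.

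With the replicate number as a block the muscle interaction had 54 genes, the kidney interaction 102 and the trap in wild-type kidney 53. The labels do not say whether these numbers mark a shared origin within a tissue. Best correlated with an array of their own number were 7 of 15 muscle and 6 of 15 kidney arrays (same-number correlations -0.24 to 0.30 and -0.12 to 0.34). The mean correlation was 0.0106 for the same and -0.0039 for other numbers in muscle, and 0.0383 and -0.0115 in kidney. No chance value was computed for these, so the question stays open.

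Of 281 results of a named gene in a tissue and comparison, the call was lost for 97 with the 18S covariate, 52 with the actin covariate, 41 with only 2 groups, 29 with a 2-fold minimum, 17 with the block, 15 with the mean of probe sets, 6 with quantile normalization, 4 with array weights and 1 with median centring. The normalization method is not given in the sources used here, the labels name no batch, and with 3 or 4 arrays per group small changes stay undetected.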

Other observations

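Top2a, Mki67, Kif20a and Ccnb2 moved apart between the genotypes in treated kidneys. Top2a, a topoisomerase of dividing cells, was at -1.27 ± 0.26 with the trap in wild type (log2 fold change ± standard error, adjusted p = 0.0306) and 0.83 ± 0.24 in mutants (adjusted p = 0.0808, not called), an interaction of 2.10 ± 0.35 (adjusted p = 0.00939). The proliferation marker Mki67 fell by 1.23 ± 0.27 in wild type (interaction 1.80 ± 0.36), the mitotic kinesin Kif20a fell by 1.40 ± 0.28 (interaction 2.21 ± 0.38) and the cyclin Ccnb2 fell by 1.47 ± 0.28 (interaction 2.10 ± 0.38). Kif20a was at 4.45 in treated wild type, under the 5.07 of fast-fibre genes in kidney, so its size is uncertain. In treated mutants against treated wild type Top2a and Mki67 were higher by 2.14 ± 0.24 and 2.13 ± 0.25 (n = 4 and 4). The cell cycle list had an interaction median of 1.29, with 16 of 31 members higher and 28 adjusted over the list alone, but adjusted p = 0.0989 with an estimated correlation. These genes were chosen after their values were seen. Their falls come from the trap in wild-type kidney, where chance was not called unlikely (2 of 35 splits). The genes called there went from 156 to 2 with the 18S covariate and lay between 24 and 408 without single arrays.

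Single genes of 2 cell types of the collecting duct were called in opposite directions in treated kidneys. No test of the difference between the 2 sets of genes was made. In treated mutants against treated wild type the principal-cell genes Aqp2, a water channel (1.43 ± 0.31), Avpr2, the vasopressin receptor (1.33 ± 0.09), and Scnn1b, a sodium channel subunit (1.09 ± 0.17), were higher. The intercalated-cell genes Slc4a1 (-2.21 ± 0.33), Slc26a4 (-1.79 ± 0.26), Rhbg (-1.31 ± 0.20), Slc4a9 (-0.89 ± 0.21), Atp6v1b1 (-0.84 ± 0.19), Foxi1 (-0.78 ± 0.19) and Atp6v0d2 (-0.67 ± 0.13) were lower (n = 4 and 4, adjusted p at most 0.0037). Under PBS Slc4a1 (-1.62 ± 0.35), Slc26a4 (-1.06 ± 0.28) and Rhbg (-0.81 ± 0.21) were lower in mutants as well, whereas Foxi1 (1.27 ± 0.21) was higher and Atp6v1b1 was at 0.17 ± 0.20 (adjusted p = 0.508). For Aqp2, Avpr2, Scnn1b, Slc4a9 and Atp6v0d2 no values under PBS are given here, so opposite directions without the trap are not shown. The genes of this paragraph were also chosen after their values were seen.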
